A study of Mus musculus with 65 samples.

How the data were processed

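The samples were muscle and brain of mice of 2 lines, each with mutant and wild-type animals at 2 ages, and each library was sequenced by itself. Per the labels' protocols, RNA was extracted from homogenised tissue, polyA RNA was selected, and libraries were sequenced as single-end reads of 70 bases. The labels' protocols do not say whether the libraries kept the strand, so a gene and its antisense partner were not told apart. Groups were taken from the labelled tissue, line, age and genotype, which gives 8 groups per tissue. The labels give 1 strain, C57BL6/J, for all animals.

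The authors aligned reads with Bowtie2 2.2.0 and estimated expression with RSEM 1.2.12, per the submitters' processing notes. The notes do not state the genome build, the annotation or any filter. Each deposited file holds 1 library with 38924 genes, and per the file headers it gives expected counts, which are RSEM's estimates of reads per gene before any normalization. The deposited files also hold TPM, which the authors' RSEM run scaled by length to a fixed sum, and FPKM, which it scaled by length and total. TPM and FPKM were not used for tests. The files pair each gene identifier with a symbol, and all 38924 were named from the files. Gene positions came from the GENCODE vM21 annotation on GRCm38, matched by gene identifier, and were used to place genes near the mutated ones and for no count.

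Expected counts from the deposited files were rounded to whole numbers. A gene with 0 counts in a library was given the limit of 3 counts, and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Single replicates of a group were compared with each other, and no pair within a group was a copy, with a lowest chi-square per gene of 5.93 over 125 pairs.

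Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test, with TMM normalization, the default low-count filter on the groups and Benjamini-Hochberg adjustment, calling genes at adjusted p under 0.05. All libraries of a tissue entered one fit with the labelled sex as a covariate, so that small groups shared an estimate of spread. The single wild-type libraries of the Pla2g6 line at week 13 are therefore assumed to vary like the other groups. The 8 comparisons of mutant and wild type, the change of the mutation effect with age and the difference between the mutations were contrasts of that fit. The difference between tissues in the Nadk2 line came from a fit of both tissues with 16 groups. Replicate numbers were checked against the animal numbers: 28 numbers were shared by a muscle and a brain group of the same line, age and genotype, and 24 of them came from the same animal. No number was shared by the mutant and wild-type groups of a comparison, so these were compared as unpaired groups. The animal as a replicate block was the alternative for the difference between tissues. No wild-type library served both lines.

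Gene lists, 43 in number, were fixed before the data were examined, as were the comparisons, tests, naming rule and 117 alternatives. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Alternatives were an estimated correlation and the rotation test fry. Members that rose or fell were counted by the edgeR test adjusted over all genes, and again adjusted over the list alone. Values per library are edgeR CPM with TMM factors unless given as CPM of the library total.

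Named genes were Nadk2 and Pla2g6, the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 1 CPM in a comparison, and the 3 members of each list with the smallest p. For contrasts of effects the 4 highest and 4 lowest were taken. Xist, Y-linked genes, symbols of predicted genes and of pseudogenes, and receptor segments of immune cells were left out of the highest and lowest. The text describes the part of these genes that carries each comparison, and other genes are given as counts.

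Alternatives tried were DESeq2 1.42.0 size factors, its Wald test, no low-count filter, a fit without sex, the first digits of the animal number as a block, only the groups compared, only the libraries of a line and tissue, and leaving out each library in turn. Another gave the animal whose sex label differed between tissues the sex of its other library. Chosen after the data were seen were fits without the muscle library with brain-like values, with sex read from Xist and Y-linked genes, and without the Pla2g6 mutant animal with intermediate Pla2g6. Further ones chosen then left out a brain library with some muscle RNA, or added a length slope or a granule cell score as covariates. The length slope of a library is the slope of its log2 expression, less each gene's median in the tissue, on log2 gene length. It was taken over genes longer than 200 bases with a median log2 value above 3. The granule cell score is the mean log2 expression of the list of cerebellar granule cell genes.

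Each test was tried first on simulated counts drawn from the means and totals of the real libraries, with 200 genes changed per comparison, 100 of them by 2-fold and 100 by 4-fold. With 17137 genes in muscle, edgeR recovered 40 and 93 of them for Nadk2 at week 5, 69 and 93 at week 11, 41 and 88 for Pla2g6 at week 6, and 10 and 63 at week 13. With 18606 genes in brain it recovered 94 and 100, 93 and 100, 88 and 100, and 65 and 96, in the same order. Further checks ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Correlations between tissues were tested with 100000 permutations. No library was left out of the counts given as designed.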

Results

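The series holds 65 bulk RNA-seq libraries from muscle and brain of 2 mouse lines, with mutant and wild-type mice at an early and a late age. The Nadk2 line carries an allele of the gene for the mitochondrial NAD kinase, which makes NADP inside mitochondria. The Pla2g6 line carries an allele of the gene for a calcium-independent phospholipase A2, which remodels membrane phospholipids. Muscle of the Nadk2 line had 6 mutant and 4 wild-type libraries at week 5, and 6 and 5 at week 11. Brain of the same line had 5 and 4 at week 5, and 6 and 5 at week 11. The Pla2g6 line had 6 mutant and 2 wild-type libraries at week 6, and 3 and 1 at week 13, in each tissue. Library totals ran from 18300000 to 29800000 expected counts, with a median of 25000000, to the nearest 100000. Group values are normalised CPM (counts scaled to a common library total), as mean ± SD over n libraries, and fold changes are log2 values of mutant over wild type.

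Nadk2 mRNA fell in Nadk2 mutant muscle at week 11, by 0.80 log2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.22e-05). It measured 19.9 ± 3.32 CPM (SD, n = 6) in mutants and 34.6 ± 4.17 CPM (SD, n = 5) in wild type, and with TMM factors all 6 mutants lay below every wild-type library. At week 5 the log2 difference was -0.38 and did not pass the edgeR test (adjusted p = 0.154). The values there were 24.1 ± 3.4 CPM (SD, n = 6) and 31.4 ± 0.969 CPM (SD, n = 3), with all 6 mutants below every wild-type library on that scale. By CPM of the library total the separation did not hold: at week 5 mutants 5 and 10 had 27.6 against 26.4 to 27.2 in wild type, and at week 11 wild type 2 had 20.8 where mutants had 17.8 to 28.2. Brain showed no change that passed, with 49.1 ± 4.39 CPM (SD, n = 5) against 43.2 ± 3.21 CPM (SD, n = 4) at week 5 and 48.3 ± 6.45 CPM (SD, n = 6) against 47.3 ± 2.81 CPM (SD, n = 5) at week 11. Pla2g6 mRNA was lower in Pla2g6 mutants in both tissues and at both ages. In muscle without the brain-like library it fell by 1.77 log2 at week 6 (edgeR adjusted p = 0.0162) and by 3.14 at week 13 (edgeR adjusted p = 0.00149). Mutant muscle had 5.81 ± 3.69 CPM (SD, n = 6) at week 6 against 19.8 ± 1.98 CPM (SD, n = 2), and 2.88 ± 0.246 CPM (SD, n = 3) at week 13 against 25.8 CPM in the only wild-type library. As designed the adjusted p was 0.154 and 0.00545, and at week 6 leaving out any of the 8 libraries but mutant 6 ended the call. In brain it fell by 1.72 at week 6 (edgeR adjusted p = 1.8e-05) and by 2.45 at week 13 (edgeR adjusted p = 3.26e-05). Brain values were 5.54 ± 2.44 CPM (SD, n = 6) against 17.9 ± 0.917 CPM (SD, n = 2), then 3.7 ± 1.11 CPM (SD, n = 3) against 18.8 CPM. With sets of animals by the first digits of their numbers as a block, or only these groups or this line in the fit, Pla2g6 passed at neither age in either tissue. The animal labelled Pla2g6 mutant, week 6, replicate 6 lay between the genotypes, with 12.6 CPM of its library total in muscle and 10.3 CPM in brain. The other 5 mutants of that age had 3.53 to 4.85 CPM in muscle and 3.97 to 4.89 CPM in brain.

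**Figure D1:**
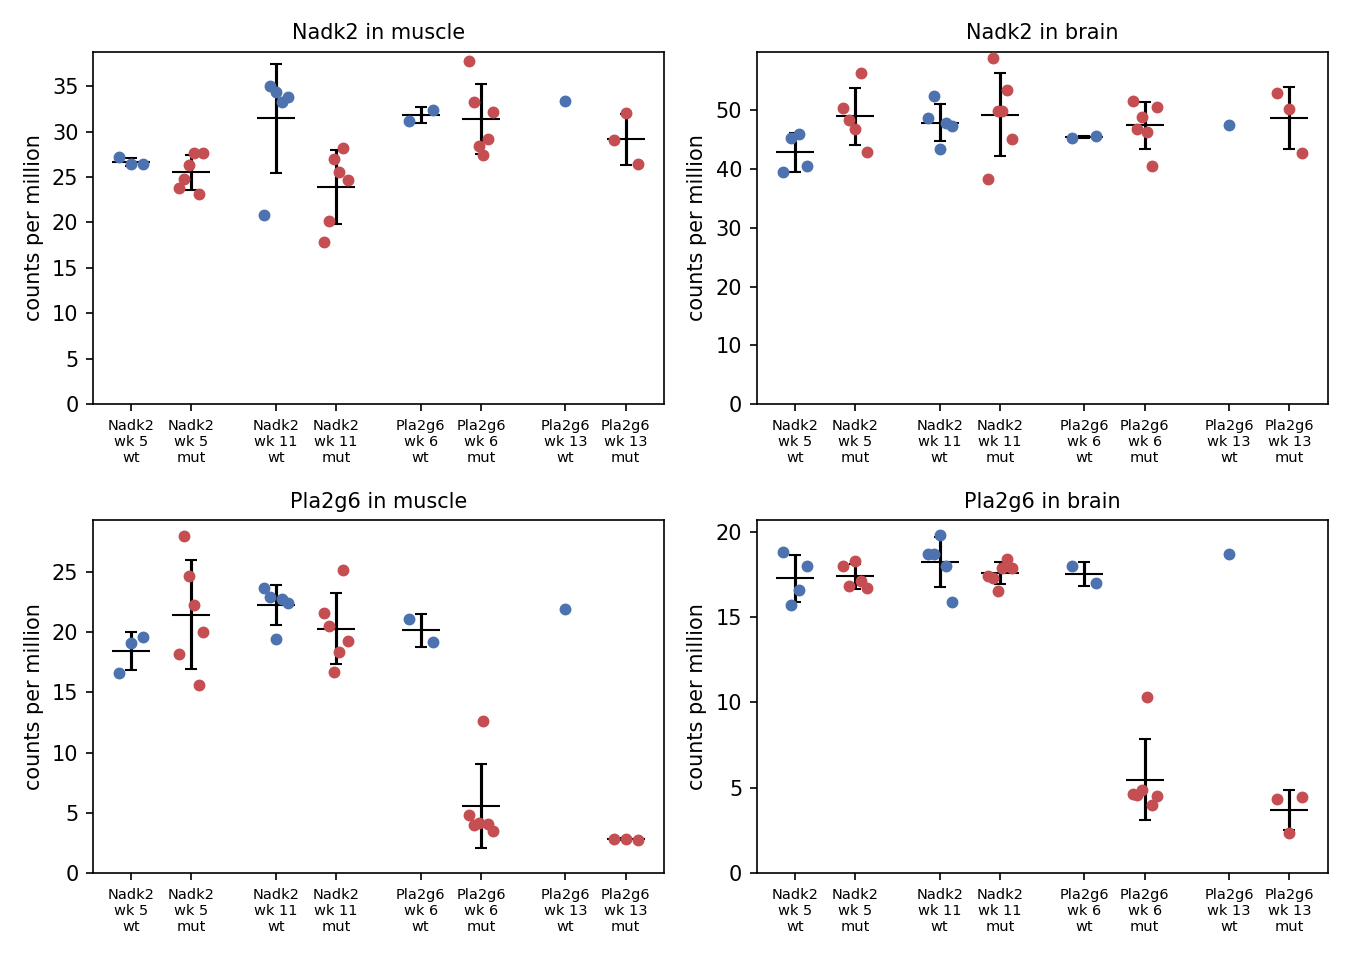
CPM of Nadk2 and Pla2g6 in muscle and brain by line, age and genotype; each point is 1 library, with the group mean and SD where a group has more than 1. Pla2g6 mutants lie below every wild-type library, and the Pla2g6 mutant at 12.6 CPM in muscle is the one at 10.3 CPM in brain.

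Tissue genes read 1 muscle library as brain. The library labelled muscle, Nadk2 wild type, week 5, replicate 9 had a median of 0.154% of the muscle level over 132 muscle-specific genes and 99.2% of the brain level over 585 brain-specific genes. Ckm, the creatine kinase of muscle, measured 4.37 CPM in it and at least 5970 CPM in every other muscle library. Snap25, a gene of synapses, measured 1620 CPM in it and at most 11.2 CPM in the others. Muscle counts are given as designed, with all libraries, and beside them without this brain-like library, a step chosen after the data were seen. Genes and lists in muscle are described from the fit without it.

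Muscle of Nadk2 mutants at week 5 had a rise of genes that muscle turns on when it loses its nerve (camera adjusted p = 1.06e-09, adjusted p = 0.265 with an estimated correlation), though mutants 7 and 10 stood near wild type. Runx1, Ankrd1, Cdkn1a and the embryonic myosins Myh3 and Myh8 rose, with macrophage genes and the ubiquitin ligase Fbxo32. Fast-fibre myosin and the glycogen genes Pygm and Phkg1 fell. Keratins of simple epithelia, Krt8 and Krt18, were among the highest rises. Among 17695 genes tested without the brain-like library 385 rose and 292 fell (edgeR, adjusted p under 0.05), with 3408 at unadjusted p under 0.05 and 1424 by DESeq2, and with DESeq2 size factors 336 rose and 368 fell. As designed, 660 rose and 2270 fell of 19116, and 342 genes were changed in both. The count moved with single libraries: without mutant 1, 2 or 3 it was 378, 392 or 415, without wild type 4, 6 or 8 it was 58, 50 or 386, and without mutant 10 it was 1442. With the animal-number set as a block, or with only the groups compared, it was 0, and with the length slope, which is low where long genes read low, as a covariate 2541.

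Krt18 rose by 9.49 log2, from 0.232 ± 0.122 CPM (SD, n = 3) to 145 ± 164 CPM (SD, n = 6), with all 6 mutants above every wild-type library (edgeR adjusted p = 0.0189). Krt8, its partner in intermediate filaments, rose by 8.60 and was above wild type in 5 of 6 mutants. Gdf5, a growth factor that restrains the loss of denervated muscle, rose by 6.42 (edgeR adjusted p = 0.0101). Col10a1, Bpifb1 and Cd101 rose too, to 4.58 ± 6.54, 12.2 ± 24.8 and 2.9 ± 3.4 CPM (SD, n = 6), from 1 or 2 counts in all wild-type libraries together. Runx1, a transcription factor that preserves denervated muscle, rose by 5.18, from 2.06 ± 0.841 CPM (SD, n = 3) to 77.3 ± 75.4 CPM (SD, n = 6) (edgeR adjusted p = 0.00566). Ankrd1, a stress-sensing protein of the sarcomere, rose by 5.27 and the cell-cycle inhibitor Cdkn1a by 3.76, each in 6 of 6 mutants. Myh3 rose by 4.35 and Myh8 by 3.22, with 1 of 6 mutants below every wild-type library for each. Fbxo32, which tags muscle proteins for breakdown, rose by 2.24 and the proteasome subunit Psmd11 by 0.95. Lgals3, Cd68 and Gpnmb, genes of phagocytic macrophages, rose by 3.30, 3.09 and 2.52. The matrix genes Timp1, Tnc and Tgfb1 rose by 2.23, 1.80 and 1.21.

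Among the genes that fell were parts of the fast contractile machinery. Myh4, the fastest myosin, fell by 1.32 log2, from 66900 ± 26900 CPM (SD, n = 3) to 26100 ± 6860 CPM (SD, n = 6) (edgeR adjusted p = 0.0184). Casq1, the calcium store of fast fibres, fell by 1.26 and the calcium pump Atp2a1 by 0.91, both in 6 of 6 mutants. Pygm, which releases glucose from glycogen, fell to 3780 ± 1420 CPM (SD, n = 6) from 7970 ± 1640 (SD, n = 3), its activator subunit Phkg1 by 1.26 and the glycolytic Pfkm by 0.84. Fgfbp1, a muscle factor that maintains the neuromuscular junction, fell by 2.00. In NADP metabolism, Pgd of the pentose phosphate pathway rose by 1.27 (edgeR adjusted p = 0.00566), the mitochondrial folate enzyme Mthfd2 by 1.62, and the nicotinamide riboside kinase Nmrk1 fell by 0.41. Slc7a5 and Trib3, targets of ATF4, rose by 1.72 and 1.56.

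Lists fixed beforehand were tested with camera at a preset correlation, and none of the 16 called here held with an estimated correlation. The denervation response rose as given above, with 17 of 28 members up and 1 down, or 22 and 3 adjusted over the list alone. Muscle macrophages rose (adjusted p = 2.91e-10, adjusted p = 0.265 with an estimated correlation), with 3 of 20 members up, or 16 adjusted over the list alone. Fast fibre genes fell (adjusted p = 2.91e-10, adjusted p = 0.114 with an estimated correlation), with 5 of 15 down, or 13 adjusted over the list alone. Glycolysis fell (adjusted p = 5.61e-08, adjusted p = 0.265 with an estimated correlation), with 5 of 25 down, or 1 up and 14 down adjusted over the list alone. Integrated stress response genes rose (adjusted p = 0.00274, adjusted p = 0.265 with an estimated correlation), with 4 of 29 up and 1 down, or 9 and 2 adjusted over the list alone. Muscle atrophy genes rose (adjusted p = 0.00391, adjusted p = 0.616 with an estimated correlation), with 5 of 26 up, or 9 up and 2 down adjusted over the list alone. Regenerating muscle rose (adjusted p = 0.0315, adjusted p = 0.616 with an estimated correlation), with 6 of 20 up, or 11 up and 3 down adjusted over the list alone. The denervation and regeneration lists share Myh3, Myh8, Myog, Myod1 and Ncam1, and the stress lists share Psat1, Mthfd2 and others with the proline and one-carbon list.

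The lists of mitochondrial energy genes fell with no single member called at this age. For nuclear OXPHOS subunits, the nuclear parts of the respiratory chain, 0 of 76 members changed, also adjusted over the list alone (camera adjusted p = 9.02e-10, adjusted p = 0.657 with an estimated correlation). The TCA cycle had 0 of 24 (adjusted p = 6.56e-09, adjusted p = 0.488 with an estimated correlation), fatty acid oxidation 0 of 27 (adjusted p = 0.00101, adjusted p = 0.648 with an estimated correlation) and the mitochondrially encoded mRNAs 0 of 13 (adjusted p = 0.00243, adjusted p = 0.616 with an estimated correlation). Lysine degradation, whose first step uses mitochondrial NADPH, had 0 of 13, or 1 down adjusted over the list alone (adjusted p = 0.00104, adjusted p = 0.265 with an estimated correlation). Vascular cells were lower, with 0 of 16 (adjusted p = 0.0397, adjusted p = 0.616 with an estimated correlation). Blood cells were higher, with S100a8 the 1 riser of 12 (adjusted p = 0.00116, adjusted p = 0.508 with an estimated correlation). Fibroblasts and extracellular matrix rose, with 3 of 24 up, or 4 adjusted over the list alone (adjusted p = 0.00774, adjusted p = 0.695 with an estimated correlation), and tendon and cartilage, with 2 of 13 (adjusted p = 0.0455, adjusted p = 0.695 with an estimated correlation). Not called by camera were Schwann cells and nerve (adjusted p = 0.0718), slow fibre (0.0769), NRF2 and redox (0.118), adipocytes (0.132), sterol synthesis (0.213), lysosome and autophagy (0.261) and NAD and NADP metabolism (0.312). The others not called were circadian clock and glucocorticoid (0.417), cell cycle (0.533), interferon response (0.704), phospholipid remodelling (0.704), iron handling (0.704) and proline and one-carbon (0.911). For NAD and NADP metabolism the mean log2 value was 0.13 while the median was -0.03 and the test pointed down.

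**Figure D2:**
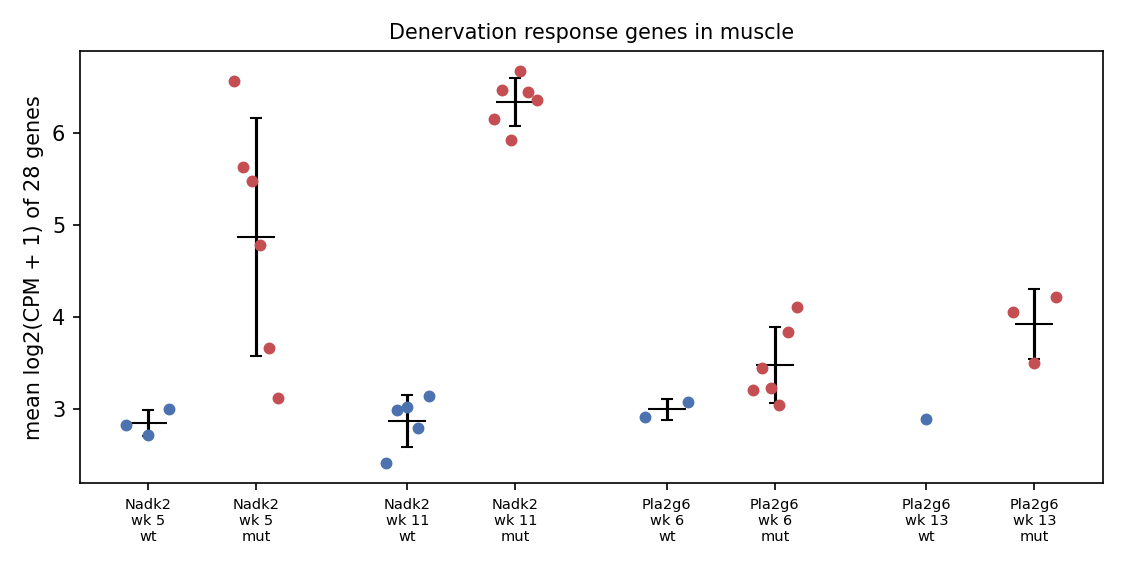
Mean log2(CPM + 1) of 28 denervation response genes in each muscle library by line, age and genotype, without the brain-like library; bars give the group mean and SD. Nadk2 mutants span 3.12 to 6.56 at week 5 and 5.92 to 6.67 at week 11, and no wild-type library exceeds 3.14.

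Denervation genes varied widely between Nadk2 mutants at week 5 and little at week 11. The mean log2(CPM + 1) of the 28 genes was 4.87 ± 1.29 (SD, n = 6) at week 5 and 6.34 ± 0.26 (SD, n = 6) at week 11, against 2.85 ± 0.14 (SD, n = 3) and 2.87 ± 0.29 (SD, n = 5) in wild type. Animal numbers of week 5 fall into sets by their first digits. In the first set the 2 mutants had 3.12 and 3.66 and the wild type 3.00, in another the mutant had 4.78 and the wild type 2.72, and the 3 animals of a set with mutants alone had 5.48 to 6.56. The score also went with the length slope: the mutants at 6.56, 5.63, 5.48, 4.78, 3.66 and 3.12 had slopes of 0.263, 0.127, -0.01, -0.119, -0.564 and -0.207.

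At week 11 every Nadk2 mutant muscle had a denervation score above all wild-type libraries, and many energy genes fell. The acetylcholine receptor subunits Chrng and Chrna1, Myh8 and the fusion protein Tmem8c rose. Genes of glycogen use, glycolysis, the TCA cycle, the respiratory chain and fat oxidation were among those that fell, with 12 of 13 mRNAs coded in mitochondrial DNA. Slow fibre genes rose in 7 of 14 members (camera adjusted p = 0.00244, adjusted p = 0.622 with an estimated correlation) and fast fibre genes fell in 11 of 15 (adjusted p = 1.03e-07, adjusted p = 0.132 with an estimated correlation). Among 17695 genes tested without the brain-like library 2194 rose and 2474 fell (edgeR), with 6532 at unadjusted p under 0.05 and 5075 by DESeq2. As designed, 1500 rose and 1110 fell of 19116 (1265 and 1331 with DESeq2 size factors), and 2604 genes were called in both. With the animal-number set as a block 896 were called as designed, and with the length slope as a covariate 7067 without the brain-like library. Of the week 5 changes, 334 genes rose and 269 fell at both ages, against 47.7 and 40.8 for independent lists, and 1 went the other way.

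Chrng, the fetal receptor subunit that returns after denervation, rose by 9.52 log2, from 0.0793 ± 0.0495 CPM (SD, n = 5) to 57.9 ± 25.9 CPM (SD, n = 6) (edgeR adjusted p = 6.9e-06). Chrna1 rose by 4.74, from 20.7 ± 2.54 to 534 ± 135 CPM (SD, n = 5 and 6), in 6 of 6 mutants. Myh8 rose by 5.98 (edgeR adjusted p = 2.01e-06) and Tmem8c, which fuses myoblasts, by 7.09 (edgeR adjusted p = 2.33e-06). Sln, which uncouples the calcium pump, rose by 8.30, and the bone growth factor genes Gdf6 and Gdf5 by 8.36 and 7.18. Col10a1 rose by 8.39, and Bpifb1 rose to 92 ± 29.9 CPM (SD, n = 6) from 1 count in 5 wild-type libraries, each in 6 of 6 mutants. Slc7a5, an amino acid carrier, rose by 2.80 (edgeR adjusted p = 5.87e-07), with Mthfd2 by 1.91 and Psat1 of serine synthesis by 1.72. Timp1 rose by 3.44, Tgfb1 by 2.01, and Ngfr, a receptor of Schwann cells that lost their axon, by 2.19. Among slow-fibre genes Pln rose by 1.83, Mb (myoglobin) by 1.47 and Casq2 by 1.37, and Car3, a carbonic anhydrase of slow muscle and fat, rose by 2.24.

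Pygm fell by 2.07 log2, from 8100 ± 1360 CPM (SD, n = 5) to 1930 ± 541 CPM (SD, n = 6) (edgeR adjusted p = 1.45e-06), Phkg1 by 2.28 and Pfkm by 1.39. Myh4 fell by 2.07, Atp2a1 by 1.41, and Mybpc2 to 1130 ± 610 from 6360 ± 1080 CPM (SD, n = 6 and 5). Citrate synthase, Cs, fell by 0.77, Idh3a by 1.34, Sdha by 0.82 and Cox7a1 by 1.66. The carnitine enzymes Cpt1b and Cpt2 fell by 1.16 and 0.86 and Acadm, which oxidises medium-chain fat, by 1.35. Sod2, the mitochondrial superoxide dismutase, fell by 1.12. Gpt2, a mitochondrial alanine transaminase, fell by 2.71 and the NADPH source Me1 by 1.29. Nmnat1, which makes NAD in the nucleus, fell by 1.06. Mstn, the brake on muscle growth, fell by 2.65 (edgeR adjusted p = 1.71e-06) and Fgfbp1 by 4.06, all in 6 of 6 mutants. The phospholipase genes Pla2g7 and Pla2g5 fell by 2.08 and 3.25. The skin keratins Krt14 and Krt17 also fell, by 4.61 and 5.16, and Krt2 and Krt25 fell to 1 and 2 counts in all mutants together, with no mutant below every wild-type library. Krt14 exceeded 1 CPM in 4 of 5 wild-type libraries and 1 of 6 mutants.

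All 15 lists called in this comparison lost the call when the correlation was estimated. The denervation response rose (camera adjusted p = 8.99e-14, adjusted p = 0.0953 with an estimated correlation), with 21 of 28 members up and 2 down, or 23 and 2 adjusted over the list alone. Regenerating muscle rose (adjusted p = 6.98e-10, adjusted p = 0.0953 with an estimated correlation), with 15 of 20 up and 2 down on either adjustment. Glycolysis fell (adjusted p = 1.06e-10, adjusted p = 0.159 with an estimated correlation), with 19 of 25 down and 1 up on either adjustment. The TCA cycle fell (adjusted p = 4.22e-10, adjusted p = 0.381 with an estimated correlation), with 21 of 24 down, or 23 adjusted over the list alone. Nuclear OXPHOS subunits fell (adjusted p = 1.22e-09, adjusted p = 0.631 with an estimated correlation), with 36 of 76 down, or 45 adjusted over the list alone. Mitochondrially encoded mRNAs fell (adjusted p = 5e-06, adjusted p = 0.379 with an estimated correlation), with 12 of 13 down, and fatty acid oxidation (adjusted p = 2.82e-06, adjusted p = 0.47 with an estimated correlation), with 15 of 27 down and 1 up.

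Smaller shifts at week 11 took in stroma and cofactor metabolism. Fibroblast and matrix genes rose in 8 of 24 members (camera adjusted p = 0.00208, adjusted p = 0.631 with an estimated correlation) and macrophage genes in 4 of 20 (adjusted p = 0.00485, adjusted p = 0.631 with an estimated correlation). Vascular cell genes fell in 8 of 16, or 9 adjusted over the list alone (adjusted p = 0.00485, adjusted p = 0.47 with an estimated correlation). Lysine degradation fell in 7 of 13, or 8 adjusted over the list alone (adjusted p = 0.0028, adjusted p = 0.359 with an estimated correlation). NAD and NADP metabolism had 12 of 32 down and 2 up, or 13 and 2 adjusted over the list alone (adjusted p = 0.0219, adjusted p = 0.47 with an estimated correlation). The interferon response had 1 of 25 down (adjusted p = 0.0356, adjusted p = 0.81 with an estimated correlation). Integrated stress response genes were not called (camera adjusted p = 0.384), with 5 of 29 up and 4 down. The muscle atrophy list was not called either (adjusted p = 0.443), with 7 of 26 up and 4 down.

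**Figure D3:**
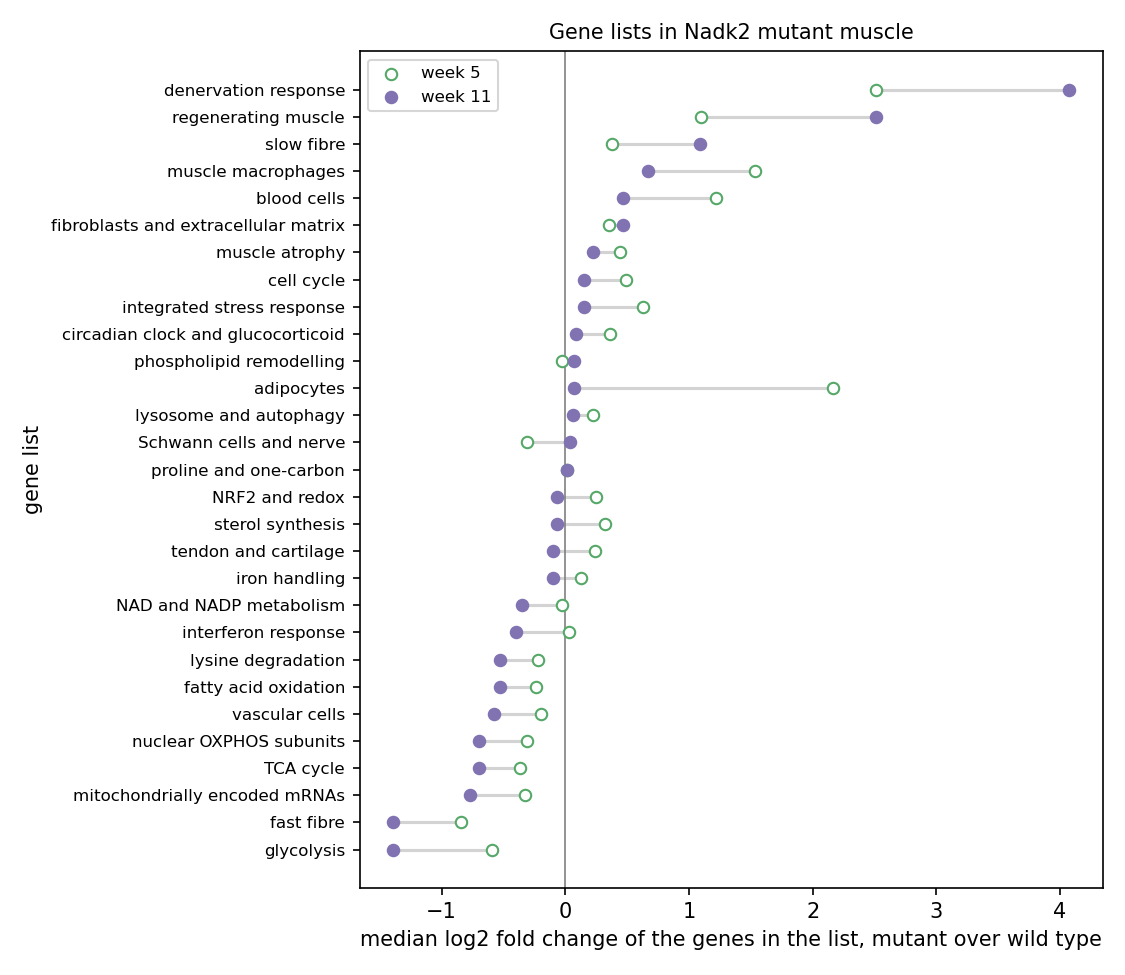
Median log2 fold change, mutant over wild type, of the genes of each list in Nadk2 mutant muscle without the brain-like library; open circles are week 5 and filled circles week 11. The denervation response lies at 2.51 and 4.07, and glycolysis at -0.59 and -1.39.

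The polyamine genes Amd1, Amd2 and Smox fell in Nadk2 mutant muscle in a way that followed sex in all other mice. Amd1 makes the aminopropyl donor for polyamines and is driven by androgens in mouse muscle. At week 5 Amd1 fell by 3.01 log2, Amd2 by 3.06, Smox, which oxidises spermine, by 2.24, and the channel genes Cacna2d4 and Kcng4 by 2.93 and 2.10. At week 11 Amd1 fell by 4.70, from 1310 ± 1170 to 44.7 ± 21.5 CPM (SD, n = 5 and 6) (edgeR adjusted p = 1.81e-05). Amd1 and Amd2 are near-identical copies that share reads, so their separate values are uncertain. By the sex read from Xist and Y-linked genes, wild-type males of the Nadk2 line had 1620 ± 498 CPM of Amd1 (SD, n = 5) and females 166 ± 49.4 CPM (SD, n = 3). Nadk2 mutant males had 93.1 ± 50.7 CPM (SD, n = 7) and mutant females 70.9 ± 37 CPM (SD, n = 5). Males that carried the Pla2g6 mutation had 1240 ± 260 CPM (SD, n = 7), with no wild-type male in that line, and their females had 180 ± 8.28 CPM (SD, n = 2). Smox and Slc30a2, a zinc carrier, split in the same way, at 437 ± 171 against 92.8 ± 15.6 CPM and 16.9 ± 2.65 against 1.44 ± 0.32 CPM in wild-type males and females (SD, n = 5 and 3). Mutant males of the Nadk2 line had 42.9 ± 19.3 CPM of Smox and 2.81 ± 1.45 CPM of Slc30a2 (SD, n = 7). These values by sex were chosen after the data were seen and no test was run on them.

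**Figure D4:**
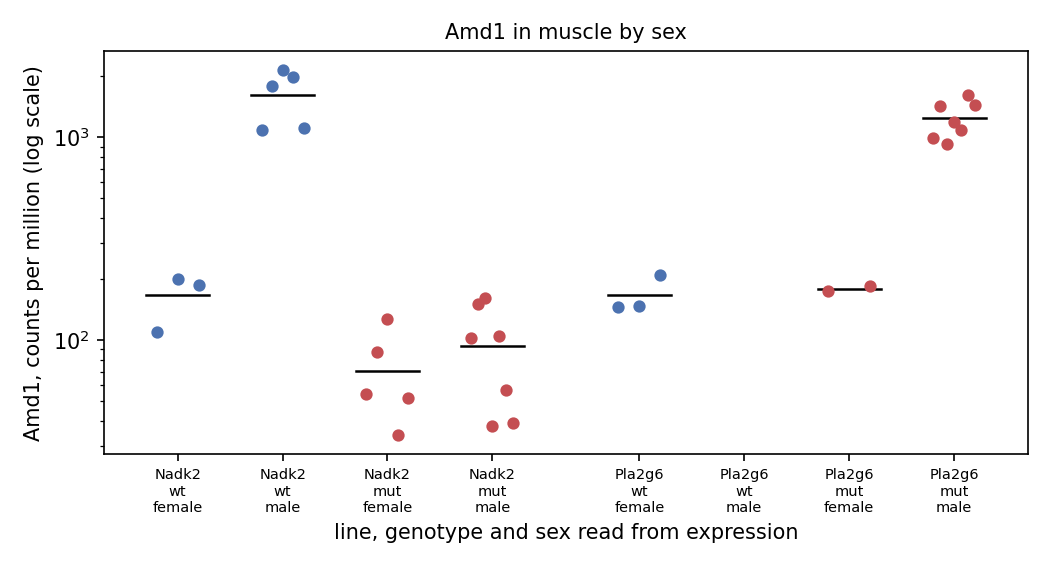
Amd1 in muscle on a log axis of CPM, by line, genotype and sex read from Xist and Y-linked genes, without the brain-like library; points are libraries and bars means. Nadk2 mutant males lie between 37.7 and 161 CPM, where wild-type males of the line lie between 1090 and 2150 CPM.

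Regeneration genes were further up at week 11 than at week 5 in Nadk2 mutant muscle, the only list whose change with age held with an estimated correlation (camera adjusted p = 1.75e-13, adjusted p = 0.0217 with an estimated correlation). Its 20 members had a median further rise of 1.24 log2, and 10 were up and 1 down adjusted over the list alone. Across all genes the edgeR test of the change with age called 0, with 1609 at unadjusted p under 0.05 and 87 by DESeq2 without the brain-like library. As designed it also called 0, with 3388 at unadjusted p under 0.05 and 1000 by DESeq2. The 677 genes called at week 5 without that library, risers and fallers together, had a median of 1.15 log2 at week 5. At week 11 their median was 1.28, counted in the direction of each gene's week 5 change. The count rested on single libraries: as designed it was 282 without week 5 mutant 1, 1114, 1194 and 985 without week 5 wild type 4, 6 and 8, and 5 without week 11 wild type 2. Without the brain-like library it was 200 and 3 without week 5 mutants 1 and 2, 5 without wild type 4 or 6, and 10 and 8 without week 11 wild type 2 and mutant 6.

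Pla2g6 mutant muscle changed in very few genes. At week 6 Pla2g6 itself fell, Rpl3-ps1, a processed copy of the ribosomal protein gene Rpl3, appeared in the mutants, and the dicarboxylate carrier gene Slc13a3 fell. At week 13 only Pla2g6 fell. Denervation genes lay higher in the mutants, at 3.48 ± 0.41 (SD, n = 6) against 3.00 ± 0.11 (SD, n = 2) at week 6 and 3.92 ± 0.38 (SD, n = 3) against 2.89 at week 13 in mean log2(CPM + 1). With 0 of 28 members changed at either age, the list was called at week 6 (camera adjusted p = 1.11e-05, adjusted p = 0.375 with an estimated correlation) and not at week 13 (adjusted p = 0.241). Leaving out the brain-like library, edgeR called 3 genes of 17695 at week 6 (1 rose and 2 fell), with 596 at unadjusted p under 0.05 and 9 by DESeq2, and 1 that fell at week 13, with 1109 and 7. As designed it called 0 at week 6, with 328 and 40, and 1 at week 13, with 633 and 63. Leaving out week 6 mutant 6 gave 2 as designed, leaving out wild type 4 or 5 gave 0 or 1 without the brain-like library, and leaving out week 13 mutant 3 or 4 gave 0 as designed.

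Rpl3-ps1 rose in mutant muscle at week 6 (edgeR adjusted p = 0.0125), to 39.8 ± 23.5 CPM of the library total (SD, n = 6) from 0 counts in 2 wild-type libraries, which allows up to 0.108 CPM. Its reads are shared with Rpl3, so the value is uncertain. Slc13a3 fell by 5.27 (edgeR adjusted p = 0.00109), from 10.2 ± 13.5 CPM (SD, n = 2) to 0.251 ± 0.171 CPM (SD, n = 6) and the fall rests on wild type 4, at 19.7 CPM of its library total. Ankrd1 and Rrad, genes of denervated muscle, had log2 values of 2.67 and 2.93 at week 6 and did not pass (edgeR adjusted p = 0.987 each). At week 13 the slow-fibre genes Tnnc1, Tpm3 and Myl3 had -2.99, -2.28 and -2.31 in 3 of 3 mutants, also short of the test (edgeR adjusted p = 0.766 each). The macrophage genes Ctss and Lyz2 had 3.49 and 2.85 there.

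Lists in Pla2g6 mutant muscle were called 15 times at week 6 and 10 times at week 13, and none held with an estimated correlation. Here sex read from expression largely went with genotype and the fit used labelled sex, so list shifts could not be told from sex. At week 6 macrophage genes were lower, with 0 of 20 changed and 1 down adjusted over the list alone (camera adjusted p = 1.47e-08). Schwann cell genes were lower, with Sox10 at -1.05 and 0 of 19 changed (adjusted p = 1.94e-08). Mitochondrially encoded mRNAs were higher, with 0 of 13 (adjusted p = 2.05e-08). Adipocyte genes were lower, with 0 of 16 (adjusted p = 1.39e-07). Each of these had camera adjusted p = 0.375 with an estimated correlation. At week 13 slow fibre genes were lower, with 0 of 14 changed and 9 down adjusted over the list alone (adjusted p = 1.42e-11, adjusted p = 0.395 with an estimated correlation). Macrophage genes were then higher, with 0 of 20 and 8 up adjusted over the list alone (adjusted p = 2.1e-10, adjusted p = 0.395 with an estimated correlation), and so were cell cycle genes, with 0 of 20 (adjusted p = 1.05e-08, adjusted p = 0.412 with an estimated correlation). Phospholipid remodelling, which holds Pla2g6, was not called at either age (adjusted p = 0.93 and 0.37), with Pla2g6 the 1 faller of 28. For blood cells at week 13 the mean log2 value was 1.37 while the median was -0.81 and the test pointed down. The change of the effect with age was called for 0 genes by edgeR, with 1225 at unadjusted p under 0.05 and 3 by DESeq2 without the brain-like library, and 0, 750 and 49 as designed. Without that library this contrast had a median of 0.07 log2 over all genes.

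Brain of Nadk2 mutants at week 5 had more haemoglobin mRNA and a mild rise of stress genes. The 4 genes called were the globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt. Targets of ATF4 rose slightly as a list, while the fall of cholesterol synthesis genes as a list was lost with an estimated correlation (adjusted p = 0.131). Neuronal and glial genes showed no single change. Of 18917 genes 4 rose and 0 fell (edgeR), with 420 at unadjusted p under 0.05 and 7 by DESeq2. Without wild type 2, 4 or 6 or mutant 5 the count was 0, and without mutant 9 it was 1. With the animal-number set as a block, or only the groups compared, it was 0. Hba-a1 rose by 1.53 log2, from 199 ± 55.6 CPM (SD, n = 4) to 571 ± 149 CPM (SD, n = 5), and Hbb-bs by 1.51, each in 5 of 5 mutants (edgeR adjusted p = 0.0345 and 0.0349). The copies Hba-a2 and Hbb-bt, which share reads with them, rose to 81.6 ± 17.2 and 59.6 ± 14.3 CPM (SD, n = 5), so the split between copies is uncertain. Alas2, which starts haem synthesis in red cells, had 1.45 and the neutrophil genes S100a8 and S100a9 0.07 and 0.35, none of which passed. Sesn2, Stc2 and Ddit3, targets of ATF4, had log2 values of 0.41, 0.54 and 0.53 and did not pass either (edgeR adjusted p = 0.201, 0.815 and 0.888).

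The stress and blood lists in this comparison, and blood cells at week 11, were the only lists between mutant and wild type whose call held with an estimated correlation. The integrated stress response rose, with 0 of 28 members called and 5 up adjusted over the list alone (camera adjusted p = 6.71e-20, adjusted p = 0.00435 with an estimated correlation). Blood cells rose, with 4 of 11 up, or 7 adjusted over the list alone (adjusted p = 3.96e-19, adjusted p = 0.00134 with an estimated correlation). Sterol synthesis fell, with 0 of 22 called and 2 down adjusted over the list alone (adjusted p = 4.12e-13, adjusted p = 0.131 with an estimated correlation). Small median shifts were called for oligodendrocytes and myelin, at -0.08 with 0 of 19 members called (adjusted p = 0.00428, adjusted p = 0.775 with an estimated correlation), and for choroid plexus and ependyma, at 0.27 with 0 of 16 (adjusted p = 0.00559, adjusted p = 0.681 with an estimated correlation). The pan-neuronal and neurofilament list had -0.08 with 0 of 17 (adjusted p = 0.0123, adjusted p = 0.131 with an estimated correlation) and reactive astrocytes 0.13 with 0 of 24 (adjusted p = 0.0125, adjusted p = 0.66 with an estimated correlation). Oligodendrocyte precursors had -0.07 with 0 of 12, immediate early genes 0.31 with 0 of 20 and synaptic calcium and channels -0.03 with 0 of 19, all at adjusted p = 0.0278. With an estimated correlation these had adjusted p = 0.66, 0.794 and 0.699. Camera did not call pituitary and meninges (adjusted p = 0.0905), resting astrocytes (0.111), forebrain neurons (0.114), microglia (0.242), cerebellar granule cells (0.647), Purkinje cells (0.727) or activated microglia (0.934). For granule and Purkinje cells the medians were 0.14 and 0.07 while the tests pointed down.

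**Figure D5:**
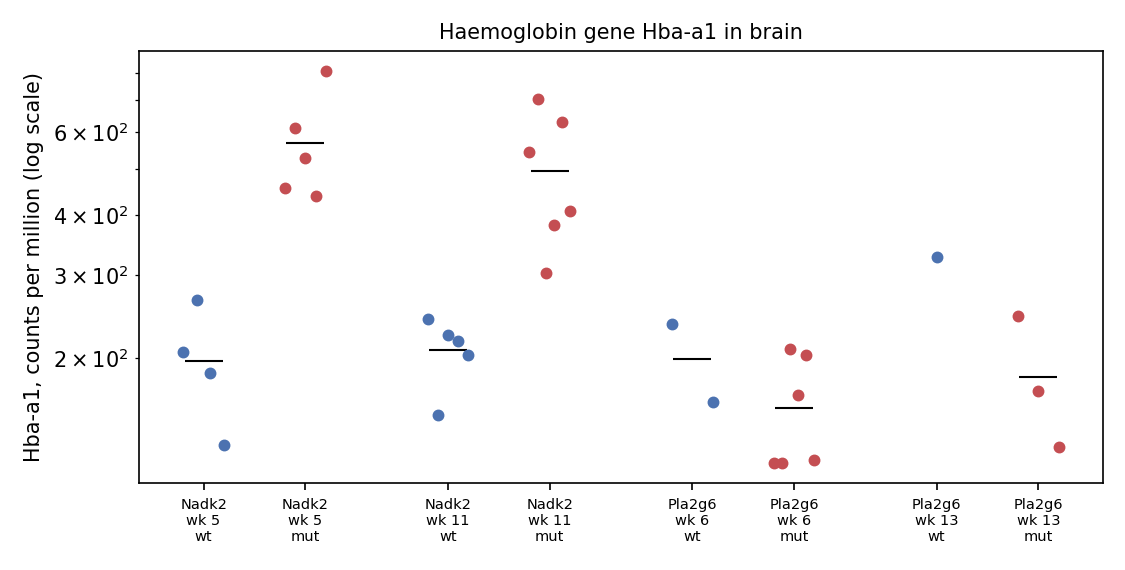
Haemoglobin gene Hba-a1 in brain on a log axis of CPM by line, age and genotype; points are libraries and bars group means. Mutants of the Nadk2 line lie above every wild-type library of their age at week 5 and at week 11.

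Brain of Nadk2 mutants at week 11 changed in 3 genes, all down, and its lists of glial activation were called but lost with an estimated correlation (adjusted p = 0.397 each). Apln, a peptide hormone of vessels and neurons, fell by 0.79 log2, from 31.7 ± 5.33 CPM (SD, n = 5) to 18.3 ± 1.21 CPM (SD, n = 6) (edgeR adjusted p = 0.00338). Hist1h2be, a histone gene, fell by 0.75 and Pm20d1, an enzyme that joins fatty acids to amino acids, by 0.80 (edgeR adjusted p = 0.00338 and 0.0416), each in 6 of 6 mutants. Of 18917 genes 0 rose and 3 fell (edgeR), with 1393 at unadjusted p under 0.05 and 60 by DESeq2, and without mutant 6 the count was 5. With the animal-number set as a block, or only the groups compared, it was 0. Hba-a1 had 1.24 log2, with 486 ± 149 CPM (SD, n = 6) against 206 ± 35.4 CPM (SD, n = 5), and did not pass (edgeR adjusted p = 0.0508). Cxcl10, C4b and Serpina3n, genes of reactive astrocytes, had 2.17, 0.86 and 0.73, and the microglial genes Cst7, Cd52 and Fcgr2b 2.64, 0.97 and 0.60, none past the test. The mitochondrial mRNA mt-Nd2 had -0.38 in 6 of 6 mutants (edgeR adjusted p = 0.228).

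Blood cells rose as a list at week 11, with 0 of 11 called and 5 up adjusted over the list alone (camera adjusted p = 9.14e-12, adjusted p = 0.0189 with an estimated correlation). Activated microglia rose, with 0 of 24 and 4 up adjusted over the list alone (adjusted p = 1.44e-05, adjusted p = 0.397 with an estimated correlation), and reactive astrocytes, with 0 of 24 and 5 up adjusted over the list alone (adjusted p = 3.2e-05, adjusted p = 0.397 with an estimated correlation). Purkinje cell genes were lower, with 0 of 25 (adjusted p = 3.51e-05, adjusted p = 0.733 with an estimated correlation), as were myelin genes, with 0 of 19 (adjusted p = 4.13e-05, adjusted p = 0.733 with an estimated correlation). Gabra6, a gene of cerebellar granule cells, was under 1 CPM in 2 of 6 mutants and 0 of 5 wild-type libraries at this age. Among libraries with cerebellum, the log2 ratio of Pcp2 to Gabra6 was -0.58 ± 0.32 (SD, n = 4) in mutants and -0.89 ± 0.11 (SD, n = 5) in wild type (exact two-sided permutation p = 0.0873). The integrated stress response had 0 of 28 (camera adjusted p = 3.2e-05, adjusted p = 0.397 with an estimated correlation). Sterol synthesis had 0 of 22 and 2 down adjusted over the list alone (adjusted p = 3.28e-05, adjusted p = 0.495 with an estimated correlation). The change with age was called for 0 genes by edgeR, with 527 at unadjusted p under 0.05 and 1 by DESeq2.

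Brain of Pla2g6 mutants changed in Pla2g6 itself and in Rpl3-ps1. Rpl3-ps1 rose to 130 ± 20 CPM of the library total (SD, n = 6) at week 6, from 0.0322 ± 0.0456 CPM (SD, n = 2) (edgeR adjusted p = 4.98e-10). At week 13 it rose to 173 ± 42.2 CPM (SD, n = 3) from 0 counts in the only wild-type library (edgeR adjusted p = 1.92e-07). The predicted gene Gm27040 was called too, at 0.538 ± 0.134 CPM (SD, n = 3) against 0 counts (up to 0.149 CPM) in that library. The call rests on it, as week 6 wild type had 0.402 ± 0.126 CPM (SD, n = 2). Both genes, outside the naming rule, were chosen after their values were seen. Of 18917 genes 1 rose and 1 fell at week 6, with 715 at unadjusted p under 0.05 and 8 by DESeq2, and with DESeq2 size factors 2 rose and 1 fell. At week 13, 2 rose and 1 fell, with 1193 at unadjusted p under 0.05 and 4 by DESeq2, which shared 1 gene with edgeR. Rpl3-ps1 took 37.3 ± 1.7% (SD, n = 8) of the reads of Rpl3 and Rpl3-ps1 together in brain of mutants other than replicate 6, and 37 ± 1.29% (SD, n = 8) in muscle. In replicate 6 of week 6 it took 16.2% in brain and 12.5% in muscle, and in wild type at most 0.0165%, where a count of 0 in a muscle library allows up to 0.203%. Rpl3 lies near Pla2g6 on chromosome 15 of GRCm38, from 80077791 to 80091868, and Pla2g6 from 79286228 to 79328390. Rpl3-ps1 lies on the X chromosome, from 13202571 to 13203780. Tfrc, the transferrin receptor, had -0.77 log2 at week 13 and Gpnmb, a gene of lipid-laden microglia, 1.75, each in 3 of 3 mutants and short of the test (edgeR adjusted p = 0.614 each).

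The lists called in Pla2g6 mutant brain numbered 12 at each age and none held with an estimated correlation. Sex was not told apart here either. At week 6 Purkinje cell genes were higher, with 0 of 25 members called (camera adjusted p = 3.23e-06). So were cerebellar granule cells, with 0 of 15 (adjusted p = 0.00401). Microglia genes were lower, with 0 of 20 (adjusted p = 0.000898), as were oligodendrocyte precursors, with 0 of 12 (adjusted p = 0.00015). With an estimated correlation these had camera adjusted p = 0.844, 0.844, 0.844 and 0.667. At week 13 immediate early genes were higher, with 0 of 20 and 2 up adjusted over the list alone (adjusted p = 1.48e-08, adjusted p = 0.596 with an estimated correlation). Activated microglia were higher, with 0 of 24 and 1 up adjusted over the list alone (adjusted p = 0.00759, adjusted p = 0.772 with an estimated correlation), and myelin genes lower, with 0 of 19 (adjusted p = 0.00549, adjusted p = 0.867 with an estimated correlation). Iron handling was not called at week 6 or 13 (adjusted p = 0.363 and 0.377). Gabra6 was under 1 CPM in 1 of 2 wild-type libraries at week 6 and in the only one at week 13. The change with age was called for 0 genes by edgeR, with 778 at unadjusted p under 0.05 and 0 by DESeq2.

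Set against each other, the Nadk2 and Pla2g6 mutations could not be compared by shared calls, since Pla2g6 had too few: by edgeR 0 genes were shared, where independent lists would share at most 0.14. Across 17695 genes in muscle the log2 values of the mutations had r = -0.051 early and 0.033 late, across genes, which are not independent replicates. By DESeq2 1 gene early and 2 late changed in the same direction there, against 0.376 and 0.937 for independent lists. A direct edgeR test of the difference in muscle called 5 genes early without the brain-like library (4 higher and 1 lower in the Nadk2 effect), with 2555 at unadjusted p under 0.05 and 349 by DESeq2. With DESeq2 size factors 2 were higher and 1 lower. Higher were Slc13a3 at 6.21 log2, which rests on Pla2g6 wild type 4, and Pgd at 1.82. So were Rgs9 at 3.86 and Clec4a3, a myeloid lectin, at 3.43, with 7 and 24 counts over all early Nadk2 wild type. Cited4, an exercise-response coactivator, was lower at -2.75 (edgeR adjusted p = 0.0408 for all 5). With sex read from expression the count was 0. Those outside the naming rule were chosen after their values were seen. Late it called 0, with 2117 at unadjusted p under 0.05 and 219 by DESeq2. As designed it called 0 early, with 2285 at unadjusted p under 0.05 and 190 by DESeq2, and 0 late, with 1176 and 100. In brain only Pla2g6 differed, by 1.70 early and 2.41 late (edgeR adjusted p = 0.00957 and 0.00128), with 337 and 1355 at unadjusted p under 0.05 and 10 and 3 by DESeq2. Blood cells rose more in Nadk2 mutant brain early, with 0 of 11 and 5 up adjusted over the list alone (camera adjusted p = 8.67e-11, adjusted p = 0.0287 with an estimated correlation). Muscle macrophages were higher in the Nadk2 effect early, with 0 of 20 and 20 up adjusted over the list alone (adjusted p = 7.76e-15, adjusted p = 0.175 with an estimated correlation), and slow fibre genes late, with 0 of 14 and 12 up adjusted over the list alone (adjusted p = 2.52e-13, adjusted p = 0.132 with an estimated correlation).

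Counts of the difference between mutations hung on single libraries. In muscle early, as designed, it was 1 without Nadk2 mutant 5 or Pla2g6 mutant 2 or 6, 2 without Pla2g6 mutant 3, 5 without Nadk2 wild type 9 and 7 without Nadk2 mutant 10. Without the brain-like library it was 153 without Nadk2 mutant 10, 3 without mutant 5, 2 without wild type 4, 1 without mutant 3, and 0 without Nadk2 mutant 1 or 2, wild type 6 or 8, or Pla2g6 wild type 4 or mutant 7 or 8. Late it was 1 as designed without Nadk2 wild type 2, and without the brain-like library 5 without that library and 93 without mutant 6. In brain it was 0 early without Nadk2 wild type 4 or Pla2g6 wild type 4 or 5, and 2 late without Nadk2 mutant 1 or Pla2g6 mutant 3.

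Without the brain-like library the Nadk2 effect differed between muscle and brain in more genes at week 11 than at week 5, and as designed in fewer, with the larger effect in muscle for the genes named here. Krt18, Krt8 and Gdf5 rose more in muscle at week 5, by 9.35, 8.22 and 6.74 log2, and Cacna2d4 fell more, by 2.92. At week 11 Sln rose more in muscle by 9.51 and Gdf6 by 8.68, and Fgfbp1 fell more by 5.25 (edgeR adjusted p = 1.72e-06, 0.00131 and 5.74e-09). With the brain-like library left out, 322 genes were higher and 199 lower in the muscle effect at week 5, and 1676 and 1858 at week 11. As designed the counts were 447 and 2854 at week 5, and 1075 and 938 at week 11 (939 and 1139 with DESeq2 size factors). With the animal as a replicate block, which pairs the tissues of a mouse, 86 were higher and 79 lower at week 5 without the brain-like library, and 41 and 10 as designed. The week 5 count without that library was 303 without muscle mutant 1, 190 and 155 without muscle wild type 4 and 6, 1134 without muscle mutant 10, and 320, 342, 339 and 292 without brain wild type 2, 3, 4 and 6.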

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

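The tests on the brain-like muscle library and on Rpl3-ps1, and the fits without that library, were chosen after the results were seen, while the tests on red cell genes and on other splits of the animals were fixed before their values were seen.

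One library labelled muscle held brain RNA. In muscle of the Nadk2 line at week 5, wild type 9 had 48.9 CPM of the library total for Nadk2 where the other 3 had 26.4 to 27.2, and it was far from them on every tissue gene. A mixed sample is argued against, since its muscle-specific genes lay at a median of 0.154% of the muscle level. A swap within the series would leave a brain library with muscle RNA, and 0 of the 32 brain libraries had muscle genes above 50% of the muscle level. Brain RNA under a muscle label remains a candidate explanation, with brain-specific genes at a median of 99.2% of the brain level (quartiles 93.7% and 105%) and r = 0.997 with the nearest brain library. It cannot be a copy of the same animal's brain library, since Gabra6, a gene of cerebellar granule cells, measured 109 CPM in it and 14.9 CPM in that library, and no biological explanation was tested.

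Rpl3-ps1 marked the Pla2g6 mutants in both tissues, and in brain Rpl3 itself was lower in all but replicate 6. In brain at week 6 Rpl3 measured 232 ± 10.5 CPM of the library total (SD, n = 5) in mutants and 402 ± 14.6 CPM (SD, n = 2) in wild type, with the intermediate animal left out, while in muscle these mutants had 35.1 to 121 against 113 in each wild type at week 6, and 60.8 to 129 against 63.7 at week 13. In brain at week 6 added expression of Rpl3-ps1 is argued against. The sum of both genes there was 370 ± 11.2 against 402 ± 14.6 CPM, a ratio of 0.921. In muscle the sum was not tested, so added expression there is open. Reads of a variant Rpl3 that are counted on its copy may explain the Rpl3-ps1 values. The share of Rpl3-ps1 differed by 0.328 percentage points between brain and muscle, although Rpl3 levels differ between the tissues. Such a variant could come with a strain interval around Pla2g6, since 12 of 219 genes within 5 Mb of Pla2g6 passed 2.5 SE in brain at week 6 against 213 of 18336 elsewhere, 4.72 times the share (Fisher exact test, adjusted p = 0.000125, across genes, which are not replicates), though Rpl3 is among the 12. The same test gave adjusted p = 0.0397 in brain at week 13, 0.0008 in muscle at week 6 and 0.668 in muscle at week 13, with 3.23% against 2.32% there, so whether changes of Rpl3, Sox10 and other neighbours come from the mutation is open.

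Red cell genes rose in Nadk2 mutant brain while neutrophil genes did not pass the test. More blood in the tissue piece should raise both, and S100a8 and S100a9 had 0.14 of the log2 value of the haemoglobin genes, but at 0.07 ± 0.65 and 0.35 ± 0.67 (SE) they vary too much to argue against it. More red cell RNA in the blood of the animals may explain the rise, since the mean log2 value of the 4 haemoglobin genes correlated between brain and muscle of the Nadk2 animals (Pearson r = 0.715, Spearman rho = 0.639, n = 19, permutation p = 0.00054 and 0.00407, adjusted p = 0.00162 for r, and r = 0.567 without the 2 farthest). Within wild type r was 0.9 and rho 0.905 (n = 8, permutation p = 0.00199 and 0.00441, adjusted p = 0.00298, r = 0.868 without the 2 farthest). Within mutants r was 0.197 and rho 0.109 (n = 11, permutation p = 0.556 and 0.755, adjusted p = 0.556, r = 0.393 without the 2 farthest), so the trend over all animals leans on wild type and on the difference between genotypes. More blood left in all tissues of an animal would give the same correlation and was not told apart.

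A sample far from the others in its group turned up 12 times in 50 tests of groups of 4 to 6 samples, where chance gives about 1 in 20, and CPM values of these samples are of the library total. The animal labelled Pla2g6 mutant, week 6, replicate 6 was far from the other 5 mutants in Pla2g6, at 10.3 CPM in brain and 12.6 CPM in muscle, and in brain also in Rpl3, at 474 CPM against 214 to 239, and in the length slope, at -0.269. Its Pla2g6 in both tissues lay between the genotypes while its brain Rpl3 lay above both, and whether its label is right was not tested. At week 11 the length slope was far off at -0.285 in brain of Nadk2 mutant 1 and -0.545 in muscle of Nadk2 wild type 2. At week 5 brain of Nadk2 mutant 7 had -0.176. Rpl3 was high in the same brain libraries, at 686 CPM against 407 to 468 and 553 CPM against 368 to 407, and in brain of Nadk2 wild type 2 at week 5, at 465 CPM against 370 to 383. Nadk2 mRNA was 20.8 CPM in muscle of wild type 2 at week 11, where the other 4 had 33.3 to 35.0 and 4 of 6 mutants had 24.7 to 28.2.

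Direct tests called differences between groups. Between mutations these were 5 genes early in muscle without the brain-like library (none with sex read from expression) and Pla2g6 in brain at each stage. The Nadk2 effect differed between muscle and brain in 3301 genes at week 5 and 2013 at week 11 as designed, and in 521 and 3534 without the brain-like library. With the animal as a block week 5 gave 51 and 165. Of the lists, 2 held with an estimated correlation. Regeneration genes were further above wild type of the same age at week 11 than at week 5 in Nadk2 muscle (median 1.24 log2, camera adjusted p = 0.0217). Blood cells rose more with the Nadk2 than the Pla2g6 mutation in early brain (camera adjusted p = 0.0287). Over the other alternatives the adjusted p of these 2 lists ran from 1.7e-13 to 0.00571 and from 4.12e-11 to 0.0773, the highest by fry in each case.

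Genotype labels were also redrawn among the animals of a line and age, with a new fit each time, and the real labels are counted among the splits. In muscle without the brain-like library chance can be excluded at week 11 (4668 genes, at most 2935 in the other splits, 1 of 60 as large). At week 5, 3 of 84 splits were as large as the real 677 genes, under that limit. Chance is not excluded there, because a split gave 2377 genes, several times the real count, which points to a structure of the samples. That split parts mutants 1, 2 and 3, the animal-number set with mutants alone, from all others, and with the set as a block the count was 0. As designed the share was under the limit for muscle at week 11 (2610 genes, at most 975, 1 of 30) but not at week 5 (2930 genes, at most 7136, 5 of 30). In the highest split of week 5 mutants 1, 2 and 3 stood with the brain-like library. In brain the share was under the limit at week 5 (4 genes, at most 1, 1 of 60) and week 11 (3 genes, at most 0, 1 of 60). Chance is not excluded there either, since the splits took no account of the animal-number sets. With these as a block both counts were 0. For the change with age the splits test nothing, since the real count was 0 and each is as large by construction: in brain at most 1 gene (40 of 40), in muscle at most 3293 without the brain-like library (40 of 40) and 900 as designed (30 of 30). Such counts in muscle again point to a structure of the samples. For the difference between tissues the share was under the limit at week 11. This held without the brain-like library (3534 genes, at most 1441, 1 of 30) and as designed (2013 genes, at most 297, 1 of 24). At week 5 it was not under the limit, without that library (521 genes, at most 768, 2 of 30) or as designed (3301 genes, at most 7656, 6 of 24). These splits took no account of the sets either.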

How the results depend on the processing

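Fits without the brain-like library, with a length slope, a granule cell score or sex read from expression, without the intermediate Pla2g6 animal and without the brain library with some muscle RNA were chosen after the data were seen, and the other settings were planned. Counts below are genes called by edgeR at adjusted p under 0.05 unless another tool is named. Where a value moved, the cause was not tested, except that leaving out libraries or groups lowers the number of samples by construction. The low-count filter left the number of tested genes between 17695 and 19116 in the fits of 1 tissue.

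Counts in muscle swung with the brain-like library. Without it the Nadk2 muscle count fell from 2930 to 677 at week 5 and rose from 2610 to 4668 at week 11. Pla2g6 muscle at week 6 went from 0 to 3, the early difference between mutations in muscle from 0 to 5, and the difference between tissues from 3301 to 521 at week 5 and from 2013 to 3534 at week 11. With it, 12 lists of Nadk2 muscle at week 5 pointed the other way, of which 7 were called with or without it. These 7 were fatty acid oxidation (camera adjusted p = 0.000103), nuclear OXPHOS subunits (0.0039), mitochondrially encoded mRNAs (0.727), the TCA cycle (0.088), glycolysis (0.813), vascular cells (0.192) and fast fibre (0.000675). Over the other alternatives their adjusted p ran from 0.00184 to 0.648, 4.14e-23 to 0.657, 0.00141 to 0.616, 7.82e-10 to 0.488, 1.47e-07 to 0.265, 0.0309 to 0.616 and 8.94e-12 to 0.114, in the same order. Slc7a5, at 1.72 log2 without that library, was -0.28 with it (edgeR adjusted p = 0.801), and the glial gene Gfap was -5.22 (edgeR adjusted p = 0.00534).

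The Nadk2 muscle call at week 5 rested on the shared fit. With only the groups compared it was 0, with and without the brain-like library, and with the first digits of the animal number as a block it was 0 in both. One of those sets held mutants alone, so the block takes out part of the difference between genotypes by construction. At week 11 the block gave 896 as designed, and the change with age in Nadk2 muscle was then 12 as designed and 134 without the brain-like library (102 up and 32 down). In Pla2g6 muscle the block gave 0 at week 13 in both fits and 0 at week 6 without the brain-like library, where only the groups compared also gave 0. The block gave 0 for the early difference between mutations in muscle without that library. In brain it gave 0 for Nadk2 at both ages, 1 for Pla2g6 at each age, and 0 for the difference between mutations at either stage. With only the groups compared brain gave 0 for Nadk2 at week 5 and 0 at week 11, and 1 for Pla2g6 at week 6. Only the libraries of that line and tissue gave 1 for Pla2g6 brain at week 13.

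DESeq2's Wald test called more genes for most counts. As designed it called 40 and 63 in Pla2g6 muscle at weeks 6 and 13, 1000 and 49 for the change with age in Nadk2 and Pla2g6 muscle, and 190 and 100 for the difference between mutations early and late. Without the brain-like library it called 1424 in Nadk2 muscle at week 5, 9 and 7 in Pla2g6 muscle, 87 and 3 for the change with age, 349 and 219 for the difference between mutations, and 971 for the difference between tissues at week 5. In brain it called 7 and 60 for Nadk2 at weeks 5 and 11, 8 for Pla2g6 at week 6, 1 for the change with age in Nadk2, and 10 and 3 for the difference between mutations. Genes called for both mutations in muscle were 0 by edgeR. By DESeq2 as designed 4 early and 2 late went the same way and 13 and 2 opposite ways, and without the brain-like library 1 and 2 went the same way and 0 opposite. On simulated muscle at week 5 DESeq2 also called 25 unchanged genes of 17137 where edgeR called 5.

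Adding the length slope as a covariate raised counts without the brain-like library to 2541 in Nadk2 muscle at week 5 (1251 rose and 1290 fell) and 7067 at week 11 (3602 and 3465). It gave 2 in Pla2g6 muscle at week 13, 41 for the change with age in Nadk2, and 317 and 120 for the difference between mutations. In brain the slope gave 80 for Nadk2 at week 11, 5 and 7 for Pla2g6 at weeks 6 and 13, and 3 and 6 for the difference between mutations. The granule cell score gave 5 for Nadk2 brain at week 11, 5 for Pla2g6 at week 13 and 2 for the late difference between mutations. Both covariates together gave 127 for Nadk2 brain at week 11 (52 rose and 75 fell), 7 and 20 for Pla2g6, and 3 and 20 for the difference between mutations. They turned around nuclear OXPHOS subunits (camera adjusted p = 0.000146, others 0.466 to 0.95) and forebrain neurons (0.992, others 0.0179 to 0.755) in Nadk2 brain at week 11. In Pla2g6 brain at week 6 they turned nuclear OXPHOS subunits (camera adjusted p = 0.00323, others 0.021 to 0.925), the TCA cycle (0.0337, others 0.473 to 0.942), NRF2 and redox (0.00927, others 0.821 to 0.965) and cerebellar granule cells (0.921, others 0.00375 to 0.87). At week 13 they turned forebrain neurons (camera adjusted p = 0.0368, others 0.885 to 0.989).

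Other settings moved small counts. No low-count filter gave 1 in Pla2g6 muscle at week 6 as designed, and without the brain-like library 1 for the change with age in Nadk2 and 0 for the early difference between mutations. It gave 5 for Nadk2 brain at week 11. DESeq2 size factors gave 1 for that change with age and 3 for that early difference. A fit without sex gave 7 for the change with age in Nadk2 muscle as designed, and without the brain-like library 1 for the same change and 9 for the difference between mutations at each stage. It gave 5 for Nadk2 brain at week 11. Sex read from expression gave 13 for the change with age in Nadk2 muscle, and 0 early and 3 late for the difference between mutations, all without the brain-like library, and 5 for Nadk2 brain at week 11. Leaving out the intermediate Pla2g6 animal gave 5 for that change with age and 2 late, and in brain 8 for Nadk2 at week 11 and 2 for the late difference. Leaving out the brain library with some muscle RNA gave 6 for Nadk2 brain at week 11. With the animal as a replicate block the week 5 difference between tissues was 51 as designed and 165 without the brain-like library. Each other pair of count and setting stayed on its side and within 1.5 times in total.

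Leaving out each library in turn gave, as designed in muscle, 677 to 4353 for Nadk2 at week 5, 1959 to 2812 at week 11, 0 to 2 for Pla2g6 at week 6 and 0 to 1 at week 13. The change with age ran from 0 to 1194 in Nadk2 and stayed at 0 in Pla2g6, and the difference between mutations ran from 0 to 7 early and 0 to 1 late. Without the brain-like library these were 50 to 1442, 3997 to 4984, 0 to 4 and 1 to 1, then 0 to 200 and 0 to 0, then 0 to 153 and 0 to 93. In brain they were 0 to 4, 2 to 5, 2 to 3 and 2 to 3, then 0 to 0 in both lines, then 0 to 1 and 1 to 2. The difference between tissues ran from 521 to 4749 at week 5 and 1676 to 2387 at week 11 as designed, and from 155 to 1134 and 3136 to 3935 without the brain-like library. The single wild-type libraries of week 13 could not be left out.

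Named genes mostly stayed on their side. Of 774 gene results 770 did so with DESeq2 size factors, with 3 newly called and 1 lost, and 740 by the DESeq2 test, with 23 newly called and 5 lost. With the animal-number block 703 stayed, 70 were lost and 1 was newly called. Leaving out libraries one at a time left 5830 values on their side, with 228 lost and 32 newly called. Of 252 list results 147 stayed with an estimated correlation and 105 were lost, and by fry 164 stayed, 87 were lost and 1 was newly called. Depth limits genes near 0: at 18300000 counts in the smallest library, a count of 0 allows up to 0.164 CPM. In Pla2g6 muscle at week 13 small changes would mostly be missed (10 of 100 simulated 2-fold changes recovered).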

Other observations

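Brain pieces differed in the regions they held, and so did muscle pieces in skin. The sets of libraries in these values were all chosen after the data were seen. Gabra6, which marks granule cells of the cerebellum, was under 1 CPM in 10 of 32 brain libraries, between 1 and 20 CPM in 2 and from 42 to 123 CPM in 20. At week 5, 2 of 5 Nadk2 mutants and 1 of 4 wild-type libraries were under 1 CPM, and at week 6, 2 of 6 Pla2g6 mutants and 1 of 2 wild-type libraries. Purkinje and granule cell genes thus vary with the piece as well as with any loss of cells. Among libraries with cerebellum, the ratio of Calb1, Car8 or Ppp1r17, genes of Purkinje cells, to Gabra6 differed by 0.06, -0.20 and 0.13 log2 between 4 Nadk2 mutants and 5 wild-type libraries at week 11 (exact two-sided permutation p = 0.714, 0.127 and 0.262).

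Pituitary hormones appeared in single brain libraries. Gh, the growth hormone, had 29.7 ± 37.9 CPM (SD, n = 4) in Nadk2 wild type at week 5 and 0.168 ± 0.233 CPM (SD, n = 5) in mutants, and Prl, prolactin, followed it with 5.46 ± 7.94 against 0.00767 ± 0.0172 CPM. The list of pituitary and meningeal genes had 5 of 15 members down adjusted over the list alone and was not called (camera adjusted p = 0.0905, others 0.201 to 0.906). Skin keratin Krt14 exceeded 1 CPM in 3 of 6 Pla2g6 mutant muscles at week 6, up to 52.8 CPM, and in 1 of 2 wild-type libraries, while it stayed under 1 CPM in all 9 Nadk2 muscle libraries of week 5 other than the brain-like one. Brain of Pla2g6 mutant 3 at week 6 had muscle-specific genes at 1.4% of the muscle level, the highest of the brain libraries.

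Sex labels and expression disagreed in part of the animals. Xist and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y contradicted the labelled sex in 17 of 65 libraries, from 9 of 33 animals. By expression all 3 wild-type animals of the Pla2g6 line were female and its mutants were 2 females and 7 males, so sex and genotype go together in that line. The Nadk2 line had 5 female and 7 male mutants and 4 female and 5 male wild-type animals. The fits used the labelled sex as designed.

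Long genes read low in some libraries. The length slope was below -0.15 in 9 muscle and 4 brain libraries, with muscle of Nadk2 mutant 7 and wild type 8 at week 5 at -0.56 and -0.37. The other muscle libraries had -0.15 to 0.26 and the other brain libraries -0.07 to 0.05. Which step of preparation lowered them was not tested, and no label gives a preparation batch.

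Contrasts of effects called many lists that did not hold. Of 252 lists tested for a change with age or a difference between mutations, camera called 84, and 2 held with an estimated correlation. In brain the length slope and granule cell score changed the direction of 1 called list in Nadk2 at week 11 and 2 in Pla2g6 at week 6.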
